A study of Mus musculus with 60 samples.

How the data were processed

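Poly(A)-enriched RNA from whole, dorsal and ventral hippocampus of mice at postnatal day 105 was sequenced in 60 libraries, 5 for each of 12 groups, as the labels state. The series record gives 5 mice for each condition, and the labels do not say whether the dorsal and ventral libraries of 1 number share a mouse. The 10 deposited tables each compare 2 groups: Handling, Restraint or Swim with Homecage in each of 3 regions, and ventral with dorsal hippocampus in Homecage mice. Per the file headers, each table gives the mean estimated count of either group, and the deposited means times 5 were multiples of 0.01 in 100% of cases. The deposited fold change is the ratio of the groups after the authors' own scaling, and the deposited log2 value is its binary logarithm, per the file headers. The deposited p-value and adjusted p come from a test by the authors whose name and model are not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2 and the mouse assembly mm8, without saying which step or file they apply to, and the aligner and counting program behind the deposited tables are not given in the sources used here.

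The tables were checked before use. They hold 13610 to 13784 genes after 144 to 148 repeated entries per table were dropped, and the Benjamini-Hochberg adjustment computed over all entries matched the deposited adjusted p. Group totals of the mean estimated counts ran from 19.9M to 25M (M, mega), and replacing the authors' scaling with total-count scaling would shift a table by at most 0.041 on the log2 scale. The smallest sum of both group means for a gene was 22.0, so the deposited tables hold no gene with fewer counts. Some items in the tables are not analysed here.

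Before the data were examined, comparisons, thresholds, 34 gene lists, alternatives and a rule for naming genes were written down. The plan had count-based tests for each pair of groups and, if only the authors' comparisons were deposited, their adjusted p at 0.05. The latter case held, so the planned count tests could not be used and the calls are the authors'. A standard error was derived from each deposited log2 fold change and p-value as the absolute fold change over the normal quantile of the p. The difference between regions was the ventral minus the dorsal log2 fold change, divided by the root of the summed squares of both errors, compared with a normal distribution and adjusted by Benjamini-Hochberg over 13500 to 13533 genes. These errors are approximate, and they ignore any pairing of dorsal and ventral libraries. Treatments were compared with each other in the same way, a test added after the files were seen, since the plan had a difference without a test. Because both tables share the Homecage libraries, that error is an upper bound.

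The naming rule takes up to 10 risen and 6 fallen genes with the lowest adjusted p per comparison, up to 4 members per list, and 11 genes always: Fos, Arc, Egr1, Npas4, Nr4a1, Sgk1, Fkbp5, Per1, Nr3c1, Nr3c2 and Ttr. Maff throughout, Klf2 in whole Restraint, Arrdc3 in whole Swim, Kl in ventral Handling, and Prox1 in the regional Homecage table fall outside it and were chosen after their values were seen. So were the genes named for being shared between tables.

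Gene lists were tested with camera on ranked statistics (limma 3.58.1, R 4.3.3), with an inter-gene correlation of 0.01 and the signed normal quantile of each p-value as the statistic. An estimated correlation could not be had without values per library, and markers of 1 tissue, such as choroid plexus, vary together more than that setting allows. Adjustment ran over the 34 lists of a table, and the counts adjusted over the list alone apply Benjamini-Hochberg to its members. Shared calls were compared with independence by Fisher's exact test, and with 100 draws of simulated groups without effect that share or do not share controls.

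After the data were seen, a correction for GC content was added. The lowess trend (fraction 0.3) of log2 fold change on the GC content of each gene's transcripts was subtracted from each table, the error was kept, and the adjustment was run again. GC content came from GENCODE M21 on GRCm38, the reference used here, and at least 99.76% of gene IDs per table had a value. The slope on GC content within a group used log2 CPM of the group means with a pseudocount of 0.5 and a minimum of 1 CPM. Implied errors of choroid plexus markers were compared with those of the 100 other genes nearest to each marker in the lower group mean. A second added alternative left out choroid plexus genes, here the markers and genes that track them by at least 1 log2 unit. For ventral tables, tracking genes were higher in dorsal Restraint than in dorsal Swim. For dorsal tables they were higher in ventral Handling than in ventral Restraint. Whole tables and the regional difference left out both sets, so the regional count rests partly on the ventral Handling values under test. The alternatives written down beforehand that could be run were an adjusted p of 0.01 and a new adjustment over genes above the median level.

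The difference tests and the GC correction were tried on simulated counts analysed with edgeR 4.0.16, with 5 libraries per group and 200 changed genes. For ventral minus dorsal (13479 genes), 95.9% of genes changed by 1 log2 unit and 76% of those changed by 0.5 were called, and 5.03% of 179 calls were unchanged genes. For 2 treatments with shared Homecage in ventral hippocampus (13513 genes) the shares were 96%, 78.8% and 0% of 174. With a GC trend added to the regional difference (13501 genes), 72.4% of 617 calls were unchanged genes, and after the correction 4.02% of 174. The added trend was linear in the same GC values and lay in ventral treatment alone. Its removal therefore does not give the error rate of the correction on the deposited values. The camera step was tried on independent normal values instead, where it gave a planted list a p of 6.3e-11 and called 4% of 100 unshifted lists at 0.05. Because those values were independent, that share does not give the error rate for lists whose members vary together. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.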

Results

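Gene expression was measured by sequencing poly(A)-enriched RNA from the hippocampus of C57BL/6 mice at postnatal day 105. The 60 libraries form 12 groups of 5, made of 3 tissue samples (whole, dorsal and ventral hippocampus) and 4 conditions. Homecage mice are the reference, and the others were taken 45 minutes after Handling, Restraint or Swim. The hippocampus holds many receptors for stress hormones, and its dorsal part is tied mainly to spatial memory and its ventral part to emotion, so the design asks which genes each treatment moves and whether both parts answer alike. The data used here are 10 tables in which the authors had already compared 2 groups gene by gene, with 13610 to 13784 genes each. Their group means sum to between 19.9M and 25M estimated counts (M, mega), which is the average depth of a library of the group over the genes held. Values of single libraries were not used here, so no spread between mice stands beside a value, and the authors' adjusted p carries the replicate error.

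In whole hippocampus, Handling raised activity-dependent immediate early genes, the transcripts that neurons switch on within minutes of firing. In the authors' deposited table Fos rose by 1.90 on the log2 scale (adjusted p 5.3e-36), Egr2 by 2.49, Arc by 1.22, Egr1 by 0.95 and Nr4a1 by 0.90. Of 24 measured immediate early transcription factors, 12 rose and none fell, and 16 rose when adjusted over the list alone (camera adjusted p 1.0e-83). Glucocorticoid receptor targets moved the same way, with 8 of 28 higher and 16 adjusted over the list alone (camera adjusted p 2.1e-28). Among them the authors' deposited table gives 0.40 for Per1, a clock gene with a glucocorticoid response element, 0.44 for Errfi1, a brake on EGF receptor signalling, and 0.39 for Sgk1, a kinase induced by corticosteroids. The falls in that authors' deposited table were led by Lsm7, part of the RNA decay and splicing Lsm ring, at -1.22, Ndn, which encodes necdin from an imprinted locus, at -0.83, and Xlr4b, an X-linked lymphocyte-regulated gene, at -2.59. In all, 54 genes passed an adjusted p of 0.05, 50 higher and 4 lower. Markers of other tissues moved as lists, choroid plexus with a median of 0.41 and 1 of 8 past the test (3 adjusted over the list alone, camera adjusted p 2.9e-08) and blood cells with 0.50 and none of 6 either way (1.1e-05). Astrocyte markers were higher as a list (0.04, 0.0182). Ventral hippocampus markers (-0.08, 0.0182) and CA1 pyramidal cell markers (-0.06, 0.0409, and 0.152 after the trend on transcript GC content was subtracted) were lower.

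Restraint in whole hippocampus raised immediate early genes together with Apold1, Cyr61 and the factors Klf2 and Klf4. The authors' deposited table puts Fos at 1.92, Egr1 at 0.75, Sik1 at 1.12 and Dusp1, a phosphatase that ends MAP kinase signals, at 1.03. Apold1, an endothelial immediate early gene, rose by 2.41 in the authors' deposited table, Cyr61, a matricellular growth regulator, by 1.85, and the shear-responsive factors Klf2 and Klf4 by 1.47 and 1.23. Endothelial cell markers as a list did not pass (none of 16, median -0.04, camera adjusted p 0.461). Immediate early factors rose in 16 of 25 cases, or 19 adjusted over the list alone (camera adjusted p 2.1e-178), and glucocorticoid receptor targets in 11 of 29, or 18 (camera adjusted p 4.3e-64), with Sgk1 at 0.86 and Tsc22d3, an anti-inflammatory leucine zipper, at 0.62 in the authors' deposited table. Hes5, a Notch target of neural progenitors and astrocytes, fell by 0.86 there, as the authors' deposited table records with an adjusted p of 7.9e-07. A total of 74 genes passed, 69 up and 5 down. Markers of other tissues shifted as lists too: choroid plexus markers had a median of 0.50 with 2 of 12 past the test, meningeal fibroblast markers 0.38 with 1 of 12, and blood cell markers 0.59 with none of 6 over all genes and 6 adjusted over the list alone.

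Swim moved 54 genes of whole hippocampus, 46 up and 8 down (44 and 4 after the trend of fold change on transcript GC content was subtracted), again led by the immediate early genes. In the authors' deposited table Fos stood at 1.95, Egr2 at 2.05, Junb at 1.14 and Nr4a1 at 0.99, and 12 of 25 immediate early factors rose, 19 adjusted over the list alone (camera adjusted p 5.2e-79). Txnip, an inhibitor of thioredoxin and of glucose uptake, rose by 0.91 and its arrestin relative Arrdc3 by 0.42 in the authors' deposited table, alongside Sgk1 at 0.81 and Nfkbia, the NF-kB inhibitor, at 0.69. Hes5 fell by 1.03 in the authors' deposited table (adjusted p 6.3e-06). Lists of small, steady shifts stood apart as well: cytosolic ribosomal proteins had a median of 0.21 (camera adjusted p 1.6e-19), the nuclear respiratory chain 0.16 (1.7e-15) and oligodendrocyte markers 0.24 (1.3e-08), though not 1 of their genes passed alone. Medians also stood at 0.84 for blood cell, 0.54 for choroid plexus, 0.39 for ependymal, 0.31 for meningeal fibroblast, 0.17 for microglia, 0.13 for astrocyte, -0.10 for dentate granule cell and -0.13 for endothelial cell markers (camera adjusted p 6.2e-04, 1.9e-04, 0.00392, 9.0e-04, 4.4e-04, 7.0e-04, 0.00536 and 8.9e-04), and fold changes fell with transcript length (rho -0.229).

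Dorsal hippocampus answered Handling with 17 genes, 16 up and 1 down. The authors' deposited table lists Egr2 at 2.96, Fos at 1.68, Fosb at 1.21, Arc, the synaptic plasticity effector, at 1.14, and Npas4, a factor tied to inhibitory synapse formation, at 0.59. Immediate early factors rose in 7 of 24 cases and in 12 adjusted over the list alone (camera adjusted p 5.6e-72). Of 28 glucocorticoid receptor targets 1 rose, or 7 adjusted over the list alone: Sgk1, at 0.36 in the authors' deposited table. Ndn alone fell, by 0.73 in the authors' deposited table (adjusted p 2.7e-04). Choroid plexus (median 0.48, camera adjusted p 2.4e-07), ependymal (0.19, 0.0496, and 0.0555 after the GC trend was subtracted), dentate granule cell (0.09, 0.00904) and astrocyte markers (0.04, 0.0154) were higher as lists, and CA1 pyramidal cell (-0.13, 0.0023) and meningeal fibroblast markers (-0.20, 0.0496) lower.

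Restraint changed 84 dorsal genes, 52 up and 32 down. The authors' deposited table is led by Apold1 at 2.34, Fos at 1.35, Sgk1 at 0.92, Tsc22d3 at 0.63, Klf4 at 1.08 and Fosb at 1.06. Immediate early factors rose in 12 of 25 cases, 15 adjusted over the list alone with 1 lower (camera adjusted p 1.2e-32), and glucocorticoid receptor targets in 6 of 29, 10 adjusted over the list alone. Xbp1, a driver of the unfolded protein response, rose by 0.34 in the authors' deposited table, as 1 of 3 risen members among 25 chaperone and heat shock genes. Hes5 fell by 1.30 in the authors' deposited table, and Sox18, an endothelial factor, by 1.01. Choroid plexus markers, whose tissue lines the ventricle beside the hippocampus, were high in the same table: 6 of 11 passed, the median was 2.68, and Ttr, the transthyretin transcript of that tissue, stood at 4.94 in the authors' deposited table. Ependymal markers had a median of 0.47 (camera adjusted p 0.00134). Subtracting the trend of fold change on transcript GC content, a step chosen after seeing the data, gave 63 up and 14 down, so that the share of rises moved from 61.9% to 81.8%.

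After Swim, 61 dorsal genes passed, 49 up and 12 down. Once the GC trend was subtracted 61 passed as well, but 40 of them were the same and 21 were new. Sgk1 led the authors' deposited table at 0.93 (adjusted p 1.1e-37), ahead of Apold1 at 1.69, Fos at 1.45, Txnip at 0.88 and Arrdc3 at 0.53. Glucocorticoid receptor targets rose in 7 of 28 cases and in 12 adjusted over the list alone (camera adjusted p 2.5e-14), and immediate early factors in 8 of 25 and in 14 (camera adjusted p 2.6e-20). Hes5 fell by 1.71 and Ndn by 0.78 in the authors' deposited table. Oligodendrocyte markers had a median of 0.26 (camera adjusted p 1.4e-08), with Mobp, a myelin protein gene, at 0.29 in the authors' deposited table as the 1 of 12 past the test, 6 adjusted over the list alone. Ribosomal protein and respiratory chain genes, higher as lists in whole Swim, were lower here (medians -0.06 and -0.08, camera adjusted p 2.3e-05 and 1.1e-04). Fold changes rose with transcript length here (rho 0.139) but fell with it in whole Swim (-0.229). A length effect on these 2 lists was not tested. Choroid plexus (median 0.45, 0.00132) and neocortex layer markers (0.06, 0.0444) were higher as lists and microglia markers lower (-0.11, 0.0286, and 0.0831 after the GC trend was subtracted). Mitochondrially encoded genes were higher (0.16, 7.4e-04), but not after that subtraction (0.947). The vesicular glutamate transporter Slc17a6, strong in thalamus and in parts of the subiculum, rose by 0.66 in the authors' deposited table, as the 1 of 8 thalamus markers past the test (2 adjusted over the list alone, camera adjusted p 0.0625, and 0.0429 after the GC trend was subtracted).

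Ventral hippocampus responded to Handling with 118 genes, 112 up and 6 down. Activity genes led it: the authors' deposited table has Egr2 at 2.69, Fos at 2.02, Arc at 1.27, Egr1 at 1.07 and Per1 at 0.56. Immediate early factors rose in 14 of 24 cases, 17 adjusted over the list alone with 1 lower (camera adjusted p 6.9e-68), and glucocorticoid receptor targets in 4 of 28, 8 adjusted over the list alone. Ndn fell by 0.75 in the authors' deposited table. All 16 choroid plexus markers measured were higher, with a median of 3.33: in the authors' deposited table Ttr stood at 5.39, F5, coagulation factor V, at 4.30, and Kl, the klotho gene, at 1.72. In whole Handling only 8 markers of this list were measured. A marker scarce in Homecage may be held only where the treated group is high, so the count of 16 may rest partly on these high values. Ependymal markers were higher as a list too (0.38, camera adjusted p 0.00738), while blood cell markers (-0.41, 0.0184) and mitochondrially encoded genes (-0.21, 2.3e-07, and 0.0184 after the GC trend was subtracted) were lower. Meningeal fibroblast markers went both ways: 1 of 12 rose and none fell over all genes, 3 were lower and 1 higher adjusted over the list alone, and the list had a median of -0.27 (0.0232). Without the choroid plexus markers and the genes that track them, 90 of the 118 calls remained. Npas4, at 0.62 in the authors' deposited table, was no longer past the test after the GC trend was subtracted (0.58, adjusted p 0.056).

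Restraint changed 329 ventral genes, 203 up and 126 down. In the authors' deposited table Apold1 stood at 2.76, Fos at 2.01, Cyr61 at 1.94, Klf2 at 1.66, Fosb at 1.46, Npas4 at 1.23, Sgk1 at 1.00 and Btg2, an antiproliferative early gene, at 0.95. Immediate early factors rose in 18 of 25 cases, or 20 adjusted over the list alone (camera adjusted p 9.9e-86), activity-regulated effectors in 14 of 30, or 21, and glucocorticoid receptor targets in 9 of 29, or 14 (camera adjusted p 2.3e-23). The falls in the authors' deposited table include Mef2c, a neuronal transcription factor, at -0.40, Camk2d, a calmodulin kinase, at -0.57, Nrep at -0.47 and Necab1, a calcium-binding protein, at -0.46, beside Hes5 at -1.09. Dentate granule cell markers rose in 3 of 12 cases and in 6 adjusted over the list alone (camera adjusted p 2.3e-05), with Prox1 at 0.28 in the authors' deposited table and 1 of 12 past the test after the GC trend was subtracted, while neocortex layer markers had a median of -0.09 with 5 of 12 lower adjusted over the list alone (camera adjusted p 0.00677). Markers of CA2 and CA3 pyramidal cells (median 0.10, 0.0339, and 0.0503 after subtraction) and of oligodendrocytes (0.10, 0.00261) were higher as lists, and those of meningeal fibroblasts (-0.27, 4 of 12 lower adjusted over the list alone, 3.5e-04) and blood cells (-0.33, 0.0286) lower.

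Swim gave 955 ventral calls, 640 up and 315 down, the most of the 9 treatment tables as deposited. Its strongest genes were again Fos at 2.06, Egr2 at 2.35, Fosb at 1.42, Apold1 at 1.77, Nr4a1 at 1.12, Sgk1 at 0.90, Txnip at 0.73 and Per1 at 0.72, all from the authors' deposited table. Immediate early factors rose in 19 of 25 cases with 1 lower (camera adjusted p 1.1e-62), activity-regulated effectors in 19 of 30 and glucocorticoid receptor targets in 12 of 29, against 20, 21 and 15 adjusted over the list alone. The falls in the authors' deposited table were led by Clk1, a kinase that phosphorylates splicing factors, at -0.47, Hes5 at -1.19 and Ndn at -0.65. Thalamus markers were lower, 3 of 8 past the test and 4 adjusted over the list alone (median -0.26, camera adjusted p 0.00173), with Slc17a6 at -0.47 and Rora at -0.33 in the authors' deposited table. Blood cell markers were lower as a list (-0.50, camera adjusted p 0.0359) and ependymal (0.29, 0.0473) and oligodendrocyte precursor markers higher (0.18, 0.0359, and 0.625 after the GC trend described next was subtracted). The fold changes of this table rose with the GC content of the transcripts (Spearman's rho across genes 0.68, genes not being independent replicates). Once that trend was subtracted 144 genes passed, 81 up and 63 down, 114 of which were among the 955. Ventral Restraint, with 247 after the same step, then had the most. The share of rises moved from 67.0% to 56.3%.

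**Figure D1:**
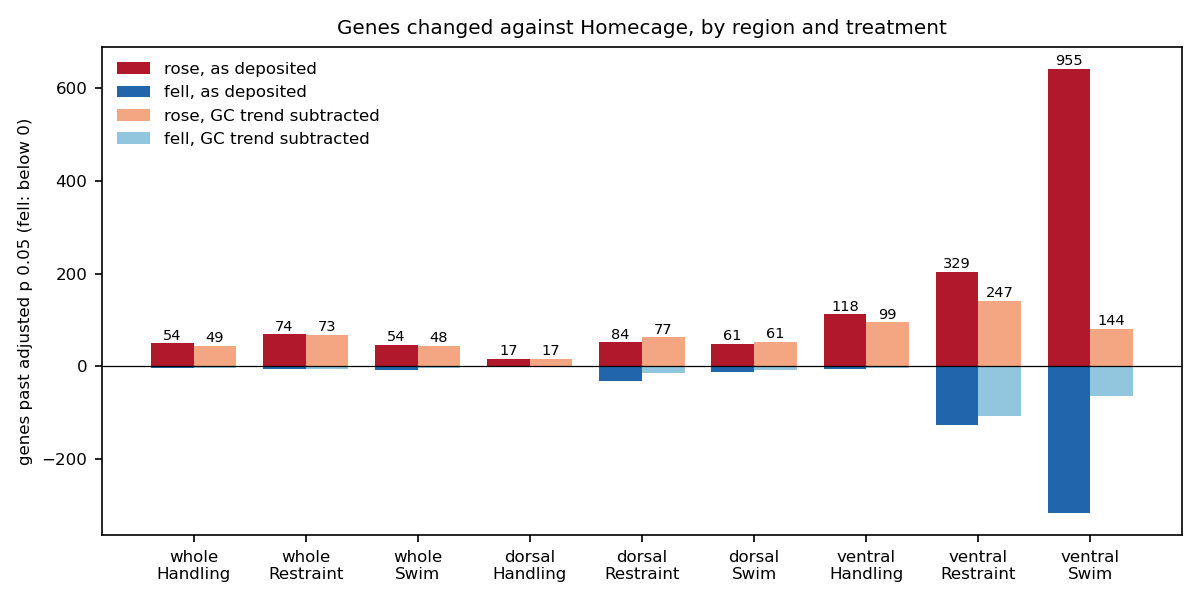
Genes past an adjusted p of 0.05 against Homecage of the same region (vertical axis, number of genes, falls drawn below 0) for the 9 treatment tables; dark bars use the deposited values and light bars the values after the GC trend was subtracted, with the total above each pair. Ventral Swim has 955 calls as deposited and 144 after subtraction, while whole Restraint has 74 and 73.

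Across the 9 treatment tables, 9 genes rose in every 1: the immediate early factors Fos, Fosb, Egr1, Egr2 and Nr4a1, the phosphatases Dusp1 and Dusp5, and the kinases Sgk1 and Sik1. Restraint and Swim together shared 19 rises over their 6 tables, which add Apold1, Cyr61, Maff, Arl4d, Cdkn1a, Dio2, Errfi1, Nfkbia, Tsc22d3 and Txnip. Hes5 was the 1 gene that fell in all 6. Cyr61, Nfkbia and Txnip passed in no Handling table, while Maff was not among the genes tested there. Handling lowered Ndn in all 3 regions, and no other gene fell in all 3. Whole hippocampus shared 42 rises between Restraint and Swim, where independent lists would share 0.22, and ventral hippocampus 132 rises and 59 falls, where 9.33 and 2.90 would be shared (one-sided Fisher's exact test, p 3.5e-129 and 9.7e-64). After the GC trend was subtracted these were 40 rises in whole and 58 rises and 20 falls in ventral hippocampus. Those tables share their Homecage libraries, so independence is too low a bar. In simulated groups without effect the whole pair gave a correlation of 0.50 and a covariance of 0.00679, against 0.60 and 0.0115 observed, and the ventral pair 0.50 and 0.00558, against 0.75 and 0.0201. No call was shared in 100 draws of either, but groups without effect yield almost no calls, so that count sets no bar. Controls could not be split, so part of the excess may come from the shared controls. Dorsal and ventral Swim, which share no library, had 28 rises in common, 3 genes called in opposite directions and a correlation of -0.24 across genes, which became 0.09 after the GC trend was subtracted.

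**Figure D2:**
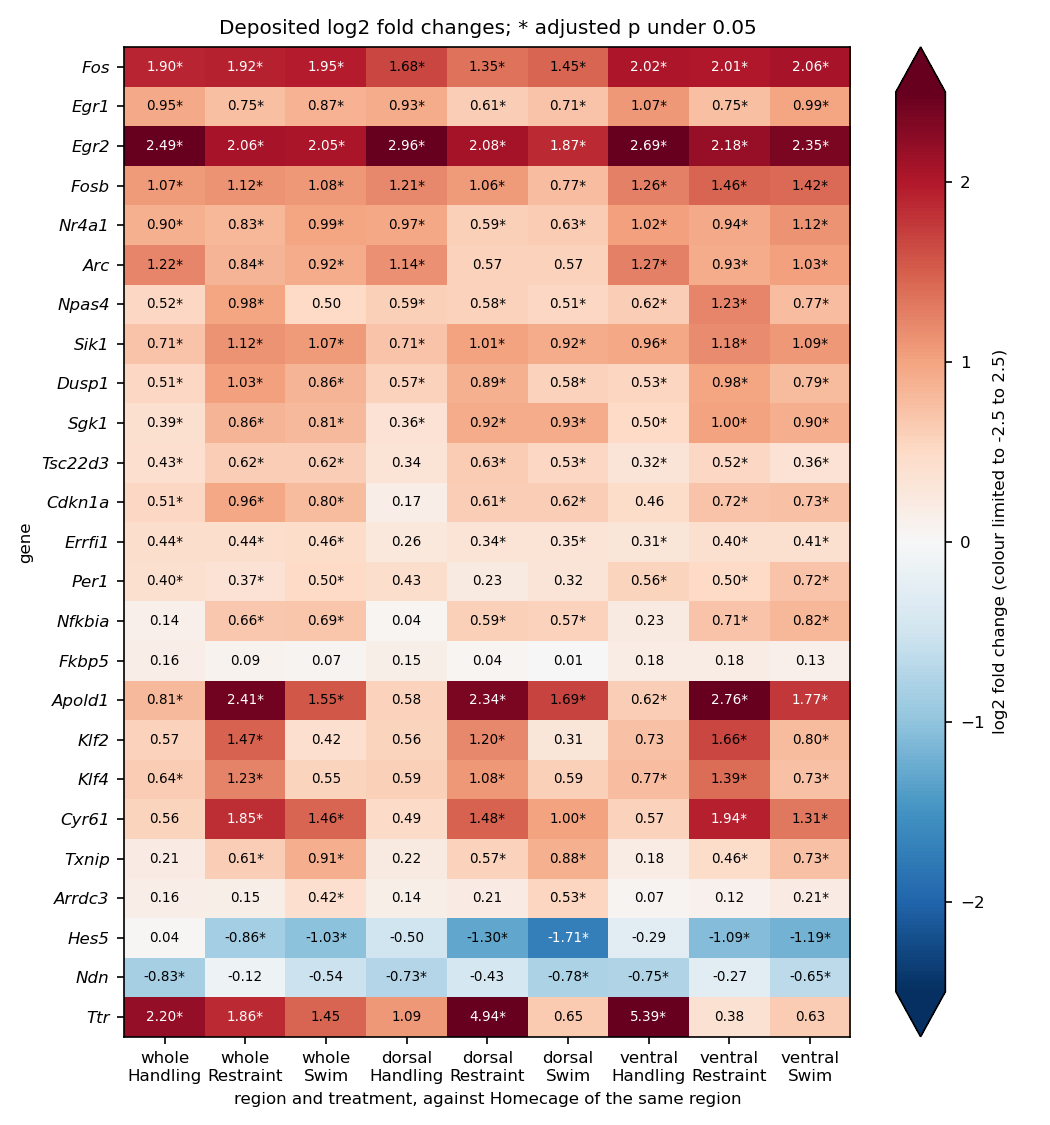
Deposited log2 fold changes against Homecage of the same region (colour and printed value) for 25 genes in the 9 treatment tables, with a star where the authors' adjusted p was under 0.05. Fos lies between 1.35 and 2.06 in all 9 columns of the authors' deposited tables, Apold1 is highest under Restraint, Hes5 is lower under Restraint and Swim, and Ttr stands out in ventral Handling and dorsal Restraint.

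Direct differences between treatments, computed from pairs of deposited tables, were few. Apold1 was higher after Restraint than after Handling by 1.61 in whole, 1.77 in dorsal and 2.14 in ventral hippocampus (adjusted p 5.5e-06, 1.6e-06 and 1.4e-10), and Sgk1 by 0.57 in dorsal and 0.49 in ventral hippocampus. Swim exceeded Handling for Txnip by 0.70, 0.67 and 0.55 in whole, dorsal and ventral tissue, each past the test. Restraint against Handling gave 4 genes in whole hippocampus (Apold1, Cyr61, Lsm7 and Nfkbia, the last no longer past the test at an adjusted p of 0.0729 after the GC trend was subtracted), 2 in dorsal (Apold1 and Sgk1) and 19 in ventral, where the 15 lower ones include Ttr, F5 and Enpp2, and 4 remain without choroid plexus genes. Swim against Handling gave 1, 3 and 16 genes, 5 of the 16 remaining without choroid plexus genes. Between Swim and Restraint no gene differed in whole or dorsal hippocampus by this normal test (92 and 73 genes at an unadjusted p under 0.05). In ventral hippocampus 1 gene did, Clk1, lower after Swim by a difference of -0.54 (adjusted p 2.1e-04, 141 genes unadjusted). The shared Homecage libraries make this test conservative, so a missing call does not show that treatments acted alike.

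Ventral and dorsal hippocampus of Homecage mice differed in 5283 of 13754 genes, 2532 higher ventrally and 2751 higher dorsally, and 4418 differed after the GC trend was subtracted (rho -0.36), 3761 of them in both and in the same direction. All 16 ventral markers were higher in ventral tissue (median 1.95, camera adjusted p 5.3e-59): the authors' deposited table gives 3.57 for Dcn, the matrix proteoglycan decorin, 3.96 for the thyrotropin-releasing hormone receptor Trhr, 2.26 for the serotonin receptor Htr2c, 2.15 for the nuclear receptor Nr2f2 and 4.22 for the Notch ligand relative Dlk1. Dorsal markers had a median of -0.43, with 5 of 9 lower and 2 higher (camera adjusted p 1.4e-05), with Lct at -2.94 in the authors' deposited table. Dentate granule cell markers were lower ventrally in 11 of 12 cases (median -0.99, camera adjusted p 2.1e-20), with Prox1 at -1.12 in the authors' deposited table, and all 12 oligodendrocyte markers were lower (median -0.56, camera adjusted p 3.9e-08), Mbp at -0.69 and Mag at -0.79 in the authors' deposited table. Interneuron markers were higher in 9 of 14 cases and lower in 2 (camera adjusted p 8.3e-04), with Calb2 at 2.43, Vip at 1.00 and Npy at -0.74 in the authors' deposited table. Calb2 is also on the list of ventral markers, so it counts in both lists. Cholesterol synthesis genes were higher in 14 of 18 and lower in 1 (median 0.31, camera adjusted p 0.00135), Sqle at 0.45 in the authors' deposited table. Monoamine and acetylcholine receptors were higher in 16 of 32 and lower in 7 (camera adjusted p 0.00248), with the nicotinic subunit Chrna4 at 0.91 in the authors' deposited table. Of the steroid receptors, the mineralocorticoid receptor Nr3c2 was lower ventrally, at -0.77 in the authors' deposited table. The list-alone counts, adjusted over the list alone, were the same for these 7 lists except for the receptors, at 17 and 8. Arc at -0.93 and Egr1 at -0.75 in the authors' deposited table were lower ventrally before any treatment.

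The difference between the regions' responses was tested gene by gene as the ventral minus the dorsal log2 fold change. For Handling 12 genes differed, all higher ventrally, with Ttr at 4.30 ± 0.97 (SE implied by the deposited p), Mfrp at 4.06 and F5 at 3.63. Without choroid plexus markers and the genes that track them 2 remained. Tracking genes were picked partly by their ventral Handling fold changes, so that drop was partly built in. For Restraint 267 genes differed, 236 higher in ventral and 31 lower, and for Swim 1383, 938 higher and 445 lower. Ventral and dorsal fold changes had opposite signs in 5 of the 12 Handling, 259 of the 267 Restraint and 1367 of the 1383 Swim calls. Several named genes had a higher log2 fold change in ventral tissue. Fos was higher by 0.65 ± 0.17 under Restraint and 0.60 ± 0.19 under Swim, and Npas4 by 0.65 ± 0.19 under Restraint. Nr4a1 was higher by 0.49 ± 0.13 under Swim, and Egr3 by 0.66 ± 0.14 under Restraint and 0.74 ± 0.16 under Swim. For Egr3 the signs were opposite, with 0.46 in ventral and -0.20 in dorsal hippocampus under Restraint, and 0.52 and -0.22 under Swim. Slc17a6 lay on the dorsal side under Swim, at -1.14 ± 0.18 (adjusted p 8.0e-06), as did Rora at -0.54 ± 0.12. The tables of both regions carry GC trends of opposite sign, with rho of -0.34, -0.46 and -0.58 in dorsal and 0.44, 0.38 and 0.68 in ventral hippocampus for Handling, Restraint and Swim. After subtraction 11, 29 and 80 genes differed, of which 11, 14 and 42 had differed in the same direction before, and the balance turned: 5 were higher ventrally and 24 lower for Restraint, 15 and 65 for Swim. The other 15 and 37 for Restraint and Swim became calls only through the subtraction, apart from 1 Swim gene that turned sign. Fos, Nr4a1 and Npas4 no longer passed after it (adjusted p of Fos 0.190 under Restraint and 0.464 under Swim, of Nr4a1 0.421 under Swim and of Npas4 0.291 under Restraint) at differences of 0.55, 0.44, 0.32 and 0.55, in a test that is also stricter per gene because fewer genes pass. Egr3 under both treatments, Btg2 at 0.53 under Swim, Slc17a6 at -1.03 and Rora at -0.52 stayed past it. The regional tests of Restraint and Swim share their Homecage libraries, so passing under both is not independent support.

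**Figure D3:**
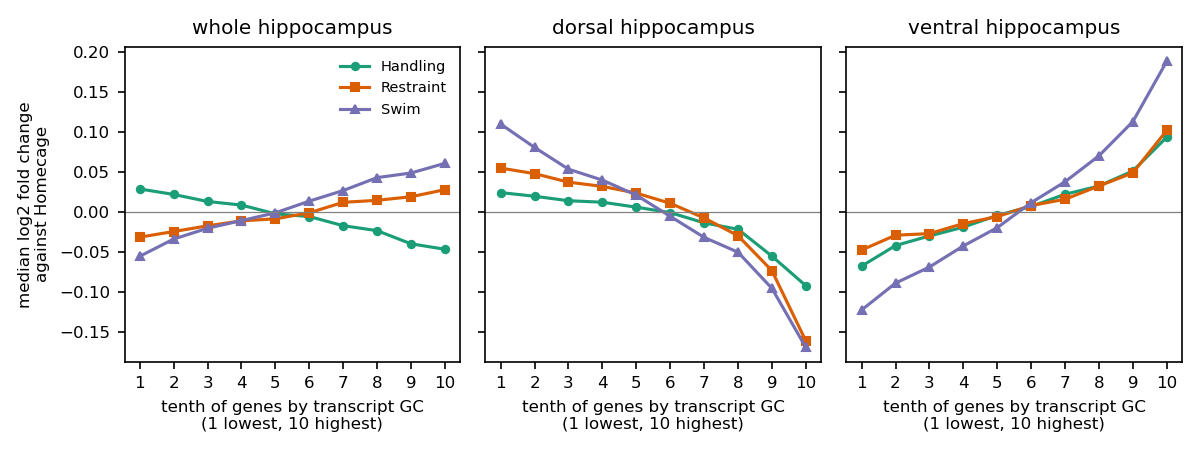
Median log2 fold change against Homecage (vertical axis) in 10 equal bins of genes by transcript GC content (horizontal axis, 1 lowest and 10 highest) for Handling, Restraint and Swim in each region. In dorsal hippocampus the lines fall and in ventral hippocampus they climb, most under Swim, where the highest bin lies at -0.17 and 0.19.

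By Ensembl gene ID, the reference annotation (GENCODE M21 on GRCm38, not necessarily the build behind the deposited tables) places Fos on chromosome 12 at 85473890 to 85477273 and Apold1 on chromosome 6 at 134981718 to 134986836. The same annotation has Sgk1 on chromosome 10 at 21882184 to 21999903, Hes5 on chromosome 4 at 154960923 to 154962371, Ndn on chromosome 7 at 62346569 to 62350262 and Ttr on chromosome 18 at 20665280 to 20674321. All 6 are annotated as protein-coding genes.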

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

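The tests named below as written afterwards are the choroid plexus response in every region and the count of genes kept in the same direction by the GC correction, and the same-direction condition was itself added after that count was first seen. The results listed here were marked because the test of ventral minus dorsal response passed an adjusted p of 0.05, which makes them differences between groups under 1 treatment.

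Under Handling 12 genes responded differently, all higher in ventral hippocampus: Mfrp by 4.06, Ttr by 4.30, F5 by 3.63, Trpv4 by 2.46, Abca4 by 2.21, Enpp2 by 2.18, Col4a4 by 1.95, Col9a3 by 1.67, Kl by 1.59 and Slc4a2 by 0.76 among them. The others were the unnamed gene models 1500015O10Rik, by 3.01, and Gm4737, by 2.62. Under Restraint 267 genes differed. Higher ventrally were Hspa1b by 1.05, Rasl10a by 0.81, Dok3 by 0.80, Adra1d by 0.78, Lmtk3 by 0.76, Egr3 by 0.66, Fos by 0.65, Npas4 by 0.65, Homer3 by 0.59, Plekhg5 by 0.50, Plch2 by 0.49 and Adam11 by 0.43. Lower ventrally were Ttr at -4.56, Lenep at -1.35, Bmp3 at -1.04, Camk2d at -0.59, Nrep at -0.49 and Mef2c at -0.42. Under Swim 1383 genes differed. Egr4 stood higher ventrally by 1.55, Ccno by 1.42, Junb by 1.40, Lmtk3 by 0.79, Shank1 by 0.63, Fos by 0.60, Plch2 by 0.58, Spns1 by 0.58, Mast3 by 0.50, Zfp523 by 0.50, Nr4a1 by 0.49, Adam11 by 0.44 and Per1 by 0.40. Rxfp1 at -1.19, Slc17a6 at -1.14, Vwc2l at -1.13, Camk2d at -0.68, Nrep at -0.61 and Plcb4 at -0.59 stood lower. Of the Restraint and Swim genes named here as higher ventrally, Egr3 under Restraint and Ccno under Swim still passed after the GC trend was subtracted; the others did not. Their differences became smaller by unequal amounts, from 0.65 to 0.55 for Fos and Npas4 under Restraint, while that of Lmtk3 went to 0.33 and 0.23, of Egr4 to 0.80, of Shank1 to 0.15, of Per1 to 0.07 and of Mast3 to -0.09, and the adjustment is stricter per gene where fewer genes pass. Of those named as lower, Mef2c under Restraint lost its call (-0.36, adjusted p 0.0636). Slc4a2, higher ventrally under Handling, lost its call too (adjusted p 0.648).

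The first pattern is the wide regional difference under Swim. A GC-dependent difference between libraries may underlie most of it, since the count went from 1383 to 80 once each table's GC trend was subtracted, and the trend within 52 markers of 4 non-neuronal cell types (slope 0.149 per 10% GC, 95% interval 0.107 to 0.19) covered the slope of all genes, 0.163. The subtracted trend did not account for 42 genes that passed in the same direction before and after, Slc17a6, Rora, Btg2 and Camk2d among them. This cannot show that another cause exists. A library difference that a smooth trend on transcript GC content misses would leave calls too, and the subtraction itself gave 37 new ones. Slc17a6 and Rora are thalamus markers, a list lower in ventral Swim (camera adjusted p 0.00173) and, after the correction, higher in dorsal Swim (0.0429). Neighbouring tissue is untested and open for them. Whether the Homecage libraries carry the offset cannot be told apart: their ventral minus dorsal slope, -0.171, lay outside the treatments' range of -0.032 to 0.106 by about the width of that range, which was the bound set. Library batches are not recorded in the labels, and a treatment effect on GC-rich genes that differs by region stays open as well.

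The second pattern is the choroid plexus genes, high in ventral Handling and dorsal Restraint. Tissue carried along in dissection is a candidate explanation: over 11 markers the CPM increases in both tables correlated with a Pearson r of 0.998 on the log10 scale, at a median ratio of 0.94 (0.77 to 1.3), though r also reflects how abundant each marker is. Their implied errors were wide, with medians of 0.61 in ventral Handling and 0.73 in dorsal Restraint, against 0.242 and 0.197 for genes matched in the lower group mean, a comparison chosen after the result was seen. A response of similar size to Handling in every region is argued against by marker medians of at most 0.48 in dorsal and whole hippocampus beside 3.33 in ventral. Those medians cover unlike sets, with 16 markers measured in ventral and 8 in whole hippocampus. The list was also higher in dorsal and whole Handling (camera adjusted p 2.9e-08 in whole), so a smaller response there stays open. A response in 1 region to 1 treatment was not tested and stays open.

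The third pattern is Ndn, lower after Handling in all 3 regions. The prediction was that more unspliced RNA or genomic DNA in Homecage libraries would lower other genes of 1 exon too. The lowest of their 3 medians was -0.066 over at least 290 genes, which argues against a large shift shared by such genes. It cannot decide on unspliced RNA, since a gene of 1 exon has no intron to retain. Genomic DNA would not act on such genes alone, so it is not settled either. A GC trend is also argued against, since the weakest of the corrected log2 fold changes was -0.70 (highest adjusted p 1.5e-04). Its log2 fold change was below 0 in all 9 treatment tables of the authors' deposited tables, past the test also in dorsal and ventral Swim but not in whole Swim (-0.54) or in Restraint (-0.12, -0.43 and -0.27 in whole, dorsal and ventral). The fall is thus not specific to Handling, and a higher level in the Homecage mice or a difference in an unrecorded batch remains open, as does a treatment response, none of which was tested.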

How the results depend on the processing

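The GC correction and the omission of choroid plexus genes were chosen after seeing the data; the other alternatives were planned. Of 221 named-gene values from the 10 deposited tables, 203 kept direction and call after the GC correction. The call was lost by 13 and gained by 5, and none turned. The regional differences named above are not among these values. Most genes named there as higher ventrally under Restraint and Swim lost their call, and the difference of Mast3 changed sign. At an adjusted p of 0.01, 202 of the 221 values kept the call and 19 lost it, and above the median level 126 of 126 kept it. Neither of these settings alters a fold change, so no sign could turn. The latter adjusts the same p-values over fewer genes, so it could hardly end a call. Of 340 list and table pairs, 130 passed as deposited, 134 after the correction and 114 in both.

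At an adjusted p of 0.01, a stricter threshold, whole Handling gave 31 genes, dorsal Restraint 39, dorsal Swim 34, ventral Handling 71, Restraint 144 and Swim 263, and the regional difference 7 for Handling, 45 for Restraint and 422 for Swim. With genes above the median level, where fewer genes are tested, whole hippocampus gave 19, 21 and 16 for Handling, Restraint and Swim, dorsal 7, 33 and 18, ventral Handling 31, ventral Restraint 192, the Homecage regions 3041 and the regional difference for Handling 3. GC corrected counts were 144 for ventral Swim, 29 and 80 for the regional difference under Restraint and Swim, and 2 for Swim against Restraint in ventral hippocampus (Clk1 and Klf2), where the subtracted trend is what moved them. Without choroid plexus genes the regional difference under Handling kept 2 genes, a drop partly built into how the tracking genes were picked. Against Handling in ventral hippocampus, 19 genes for Restraint and 16 for Swim became 4 and 5 without choroid plexus genes, and 4 and 6 above the median level. In whole and dorsal hippocampus the comparisons with Handling, of 1 to 4 genes, moved by 1 to 4 genes where they moved. The falls in whole Swim went from 8 to 4 after the GC correction, and in dorsal Restraint from 32 to 14. Total counts not given here stayed within 1.5 times of the reported ones under these alternatives.

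No paired analysis was possible because the tables hold group means and no values per library. For the same reason the other normalization, DESeq2, low-count filters, replicate block, 4-group fit, choroid plexus covariate, leave-one-out, other splits of the samples, fry and an estimated correlation were not run, and pseudocounts do not apply. The tables hold only genes whose 2 group means sum to at least 22.0 counts, and what set that floor is not given.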

Other observations

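All tests of this part were planned except the GC correction, chosen after the data were seen. Regional Homecage differences reach further cell types and transmitter systems. Microglia markers were lower in ventral hippocampus in 9 of 12 cases and meningeal fibroblast markers higher in 8 of 12 (camera adjusted p 0.00392 and 4.4e-04), C1qa, a complement gene of microglia, at -0.46 in the authors' deposited table. CA2 and CA3 pyramidal cell markers were lower in 8 of 12 and higher in 3 (0.0198), neocortex layer markers higher in 8 of 12 and lower in 2 (0.00677), and cytosolic ribosomal protein genes lower in 20 of 78, or 16 adjusted over the list alone (0.023). GABA receptors were higher in 7 of 15 and lower in 4 (0.0383, and 0.213 after the GC correction), with the subunit Gabra3 at 1.40 in the authors' deposited table. Activity-regulated effectors were lower in 15 of 30 and higher in 3 (0.00248).

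Other lists mixed rises and falls in the same table without passing camera: glutamate receptors 12 and 7 of 24 (adjusted p 0.142), CA1 pyramidal cell markers 2 and 5 of 8 (0.157), thalamus markers 4 and 2 of 8 (0.142), striatum and amygdala markers 6 and 4 of 12 (0.753), stress peptides and corticosteroid receptors 6 and 8 of 23 (0.277), circadian clock genes 4 and 7 of 18 (0.637), chaperones 8 and 5 of 25 (0.62), histone and DNA modifiers 5 and 7 of 20 (0.522), inflammation and NF-kB genes 2 and 4 of 9 (0.232), and oligodendrocyte precursor markers 1 and 4 of 9 (0.348). Ependymal markers rose in 4 of 8 (0.232), astrocyte markers in 1 of 12 with 1 lower (0.753), endothelial markers in 1 of 16 with 1 lower (0.994), respiratory chain genes in 11 of 85 with 7 lower (0.728), mitochondrially encoded genes in 1 of 15 (0.142), and neither cold-inducible RNA-binding gene nor any of 6 blood cell markers passed.

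The glucocorticoid receptor chaperone gene Fkbp5 and the receptor gene Nr3c1 did not pass against Homecage in any of the 9 treatment tables, Fkbp5 lying between 0.01 and 0.18 in the authors' deposited tables. Of 1238 genes called in at least 1 treatment table, 982 were called in exactly 1, and 733 of these in ventral Swim. After the GC correction the counts were 440, 299 and 48. Mitochondrially encoded genes had a median of -0.16 in ventral Swim (camera adjusted p 5.1e-04), which moved to an adjusted p of 0.652 after the GC correction.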
